A study of Homo sapiens with 38 samples.

How the data were processed

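RNA was measured by sequencing in MCF7 and TamR cells (26 libraries, 13 groups), in T47D cells (8 libraries, 4 groups) and in a patient-derived xenograft of breast cancer (4 libraries, 2 groups). Per the labels' protocols, MCF7 and T47D grew in RPMI with full serum, and TamR in phenol-red-free medium with charcoal-stripped serum and 100 nM 4-hydroxytamoxifen. Cells took up shRNA lentivirus and were selected with 1 µg/ml puromycin for 3 days, or 24 h before JUN induction in the combined experiments, and JUN was induced with 1 µg/ml doxycycline for about 48 h. The hormone-independent xenograft had grown out from the same model without estrogen. A scrambled shRNA served as control for the knockdowns in MCF7, TamR and T47D, and whether those controls were also selected with puromycin is not stated. A label of every library reads full media, which for TamR is at odds with the growth protocol. The reference TamR libraries carry no shRNA in their labels and were set against scrambled-shRNA MCF7 with an uninduced JUN cassette. Groups were taken from the sample titles and treatment labels.

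The deposited tables hold raw counts of reads per gene symbol, as whole numbers with a different total in each library, and 27140 genes in each table. Per the submitters' processing notes, the genome build was hg19 and CASAVA, STAR 2.5.2b, featureCounts and DESeq2 were used, with no roles given. The annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners may share reads. Per the labels' protocols, T47D and xenograft libraries were made with an mRNA kit, and MCF7 and TamR libraries with either an rRNA-depletion kit or an mRNA kit, without saying which library had which. How reads of mouse host cells were treated in the xenograft is not given either. A length column beside the counts was not used. Because the reference at hand is of another build, no coordinates are given. It served only for gene names and for finding Y-linked genes: 110 genes per table, the Y-linked ones with XIST and TSIX, were left out.

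Each table was fitted separately with all its groups in one model, which gave 13, 4 and 2 residual degrees of freedom for MCF7 and TamR, T47D and the xenograft. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood fit and F-test, Benjamini-Hochberg adjustment, threshold 0.05), over 15942, 14002 and 14827 genes after filtering. The number changed at least 2-fold is given beside the number called, because with such close libraries very small differences pass. The T47D minus MCF7 difference was tested with a z test on the 2 log2 changes and their standard errors. The 18 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists and comparisons of one table: 107 of 180 tests were called in MCF7 and TamR, 39 of 72 in T47D and 8 of 18 in the xenograft, of which 96, 18 and 0 held with an estimated correlation. The count over each list alone was the same in 223 of 270 tests and differed by at most 3 genes in the other 47. Differences of lists between lines and between experiments used camera's rank test and were chosen after seeing the data, as were list medians at bounds, list tests without the manipulated gene and all shared calls other than those of TamR with the combined change over all calls.

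The designs, lists, comparisons and alternatives were fixed before the data were examined. Genes were named by this rule: GATA3, JUN and ESR1 in each comparison, the 5 largest rises and 5 largest falls by fitted change among called genes with a mean of at least 5 CPM and no overlap between libraries (uncharacterized, small RNA, antisense and pseudogene names left out), and per list up to 4 members with the smallest adjusted p. For interactions the 5 genes with the smallest adjusted p were taken. The text names a selection from these, made after the values were seen, and MALAT1, NEAT1, RMRP, RPPH1 and SCARNA2 were added after seeing the data. A fold against a group with no counts is a lower bound computed from a floor of 3 counts over the group, and a fold against 1 to 3 counts has a 95% exact counting interval; both cover counting error only. Older symbols in the lists (IL8, CCN1, CCN2, ERO1L) were matched to CXCL8, CYR61, CTGF and ERO1A, and RN7SK, RN7SL1 and RN7SL2 were not matched to any gene. The lists overlap in part.

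The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, other sizes of the TamR lists and an estimated correlation. Between the 2 libraries of a group the coefficient of variation beyond counting was 0.602 to 2.55%, and the chi-square per degree of freedom over genes with at least 20 counts was 1.08 to 1.77, above counting noise in all 19 groups, so no pair was merged. The procedure was tested on simulated counts with 50 genes changed at each fold. At 1.25, 1.5, 2 and 4-fold it recovered 40, 68, 72 and 82% of changed genes for the combined change in MCF7 (15013 genes, 8 false calls), 48, 70, 82 and 98% for T47D (13747 genes, 5 false calls) and 56, 70, 86 and 96% for the xenograft (14602 genes, 1 false call). With no change simulated, 0, 0 and 1 genes and 0 of 18 lists were called, and the difference test called 0 of 13505 genes, with 4.89% at an unadjusted p under 0.05. Only 200 genes changed, evenly up and down, with dispersions from these libraries. Not tested were scaling where most genes change, variation between separate cultures and the difference test on changed genes.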

Results

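Gene expression was measured by RNA sequencing in 38 libraries, 2 for each of 19 groups. Of these, 26 libraries in 13 groups came from MCF7, an estrogen receptor positive luminal breast cancer line, and from TamR, its tamoxifen-resistant counterpart, which was kept in 100 nM 4-hydroxytamoxifen. Another 8 libraries in 4 groups came from T47D, a second luminal, estrogen receptor positive line, and 4 libraries in 2 groups from a patient-derived xenograft, a human tumour grown in mice. The total count per library was 10253243 to 17296790 for MCF7 and TamR, 9084419 to 13678631 for T47D and 14102626 to 16262562 for the xenograft. The manipulations were a lentiviral short hairpin RNA (shRNA) against GATA3 or JUN, a doxycycline-induced JUN cDNA, and both together in factorial experiments (neither, each alone, both). GATA3 is a transcription factor of luminal cell identity, JUN is a subunit of the AP-1 transcription factor, and ESR1 encodes estrogen receptor alpha. Levels are normalized counts-per-million values (CPM) as mean ± SD over the 2 libraries of a group, medians of gene lists are median log2 fold changes, and a gene or list is said to rise or fall where its adjusted p was under 0.05. Where genes with 3 or fewer counts in a group moved a list's median by over 0.05, the median with them at their bound follows. Interactions and line differences were not so checked. Counts of list members up or down are calls over all genes tested, and the count adjusted over the list alone was the same unless it is given. Standard errors (SE) of log2 changes are derived from the F statistic. They can lie below counting error, above all for large changes against few counts. The small nuclear and nucleolar RNAs RMRP, RPPH1 and SCARNA2 had a median of 2333 to 5527 CPM of the total in 8 groups of MCF7 and TamR, and of 0.415 to 2.27 in the factorial experiment, the reference TamR libraries, T47D and the xenograft. Judged by these 3 RNAs, each comparison lies within one of these kinds, but differences between the stand-alone and the factorial experiments cross them. The 2 libraries of a group differed by little more than counting noise, and nothing in the labels says that they came from separate cultures or tumours, so p-values measure only the spread between these libraries, which may be technical.

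GATA3 was far lower in TamR than in MCF7. It stood at 1575 ± 20.1 CPM in MCF7 and 39.2 ± 1.08 in TamR, at 1548 ± 16.5 and 26.9 ± 0.391 with a scrambled shRNA, and at 1009 ± 10.9 in the uninduced control of the factorial experiment against 37.5 ± 2.09 in the reference TamR libraries. JUN was not consistently higher in TamR. Its levels were 100.3 ± 7.03 against 181 ± 1.31 CPM, 68.2 ± 0.0633 against 63.8 ± 0.571 CPM and 95.5 ± 5.12 against 116 ± 0.743 CPM in the 3 sets, a fall in the first and last and a difference that did not pass in the middle one, although it passed as a rise of 0.13 (log2) without the low-count filter and in a fit of those groups alone. ESR1 fell 2.69-fold, 1.70-fold and 1.68-fold. The shRNA against GATA3 left 303 ± 4.75 CPM in MCF7 (5.11-fold lower), 222 ± 3.97 in the factorial experiment (4.54-fold) and 61.5 ± 3.37 against 604 ± 0.346 in T47D (9.78-fold). The shRNA against JUN left 18.5 ± 0.122 CPM in TamR (3.68-fold lower). Doxycycline raised JUN to 834 ± 5.64 CPM from 65.1 ± 2.44 in MCF7, to 940.4 ± 18.6 from 116 ± 0.743 in the factorial experiment, and to 1878 ± 13.1 from 68.6 ± 0.172 in T47D. With GATA3 knocked down it reached 1425 ± 47.9 CPM in MCF7 and 2660.3 ± 37.4 in T47D. Reads from the introduced JUN cDNA and from the endogenous gene are not separated. Every targeted gene moved as its label states.

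**Figure D1:**
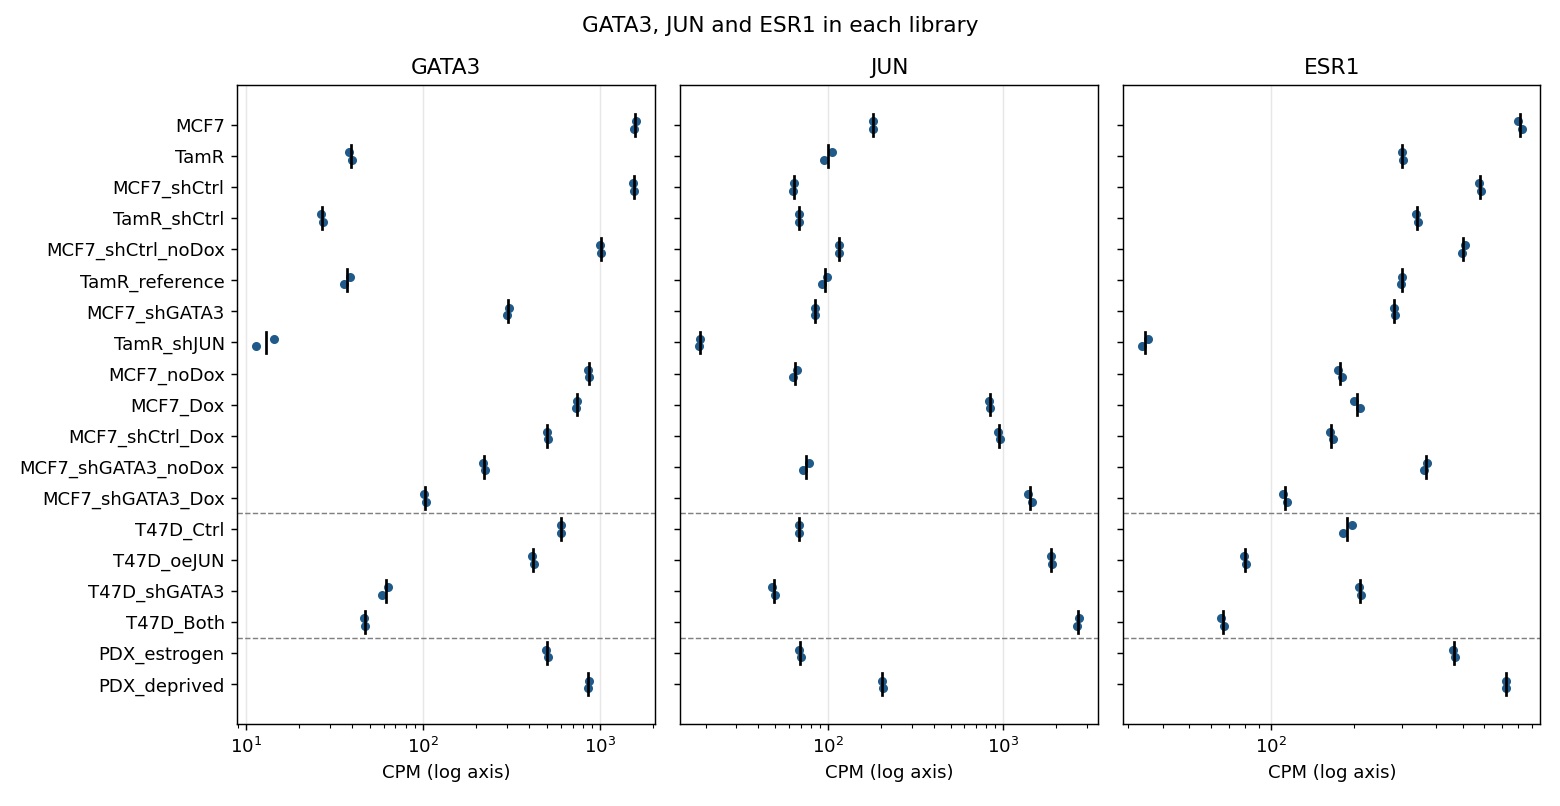
Normalized counts-per-million values (CPM) of GATA3, JUN and ESR1 (log axis) in the 38 libraries, by group. Dots are libraries, black bars the mean of the 2 libraries of a group, and dashed lines separate MCF7 and TamR, T47D and the xenograft. GATA3 lies at 1575 ± 20.1 CPM in MCF7 and 39.2 ± 1.08 in TamR, and JUN at 1425 ± 47.9 in MCF7 and 2660.3 ± 37.4 in T47D with both changes.

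The comparison of TamR with MCF7 asks how the resistant line differs from its parent. Estrogen receptor target genes were much lower in TamR. Of the estrogen receptor targets, 30 of 38 measured members fell and 7 rose (median -2.33, adjusted p = 1.31e-14). CA12, a carbonic anhydrase, was 218-fold lower (2.22 ± 0.222 against 487 ± 4.31 CPM), the chemokine CXCL12 1727-fold lower and the RET co-receptor GFRA1 29.9-fold lower. SUSD3, which lies on the same list, had no counts in TamR and was at least 1063-fold lower. Mesenchymal genes rose as a list, although not all members did. FN1, which encodes fibronectin, stood at 8289.8 ± 25 against 18.7 ± 2.94 CPM (449-fold higher), the collagen cross-linking enzyme LOX was 92.4-fold higher, while the matrix protein THBS1 was 16.7-fold lower. Of the mesenchymal list, 19 of 30 measured members rose and 4 fell (median 1.34, adjusted p = 2.63e-04).

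AP-1 target genes were higher in TamR as well. The ERK phosphatase DUSP6 was 102-fold higher, PHLDA1 48.1-fold higher and CXCL8, which encodes interleukin-8, 523-fold higher (143 ± 2.74 against 0.267 ± 0.0413 CPM). Of the AP-1 target genes, 25 of 36 measured members rose and 7 fell (median 1.37, adjusted p = 1.34e-04). AP-1 family members gave no set-level call, 12 of 19 up and 6 down (median 0.26, adjusted p = 0.567), and MAF was 2438-fold higher (95% counting interval 437 to 96342). Interferon-induced genes were lower: 30 of 38 measured members fell and 1 rose (median -3.27, or -3.02 at the bounds, adjusted p = 1.47e-08, and adjusted p = 0.0735 with an estimated correlation). IFI6 was 104-fold lower, IFITM1 59.2-fold lower and ISG15 14.6-fold lower. The p53 targets were lower too, 21 of 25 down and 2 up (median -1.08, adjusted p = 2.64e-08, 3 up and 21 down adjusted over the list alone). The stress cytokine GDF15 was 12.8-fold lower and the cell cycle inhibitor CDKN1A 2.07-fold lower. Integrated stress response genes were higher, 24 of 30 up and 5 down (median 0.78, adjusted p = 7.26e-09), among them the serine synthesis enzyme PHGDH (4.90-fold) and the cystine transporter SLC7A11 (6.34-fold). Cell cycle genes rose in this set, 36 of 45 up and 1 down (median 0.65, adjusted p = 6.01e-07), with RRM2 (6.54-fold), a ribonucleotide reductase subunit, and MCM4 (2.30-fold), part of the replicative helicase.

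Luminal genes fell, 20 of 36 down and 12 up (median -0.48, adjusted p = 2.91e-04). The anti-apoptotic gene BCL2 was 188-fold lower and the retinoic acid binding protein CRABP2 677-fold lower, whereas AGR2, an endoplasmic reticulum protein of secretory epithelium, was 6.66-fold higher. Stem and progenitor genes rose, 15 of 23 up and 5 down (median 1.32, adjusted p = 0.00742, and adjusted p = 0.0727 with an estimated correlation). The other lists gave no call as sets. Basal genes had 14 of 29 up and 11 down (median 0.72, adjusted p = 0.332), receptor tyrosine kinases and ligands 17 of 30 down and 9 up (median -0.48, or -0.39 at the bounds, adjusted p = 0.301) and NF-kB genes 11 of 23 down and 3 up (median -0.69, or -0.13 at the bounds, adjusted p = 0.461). Among the receptors, EGFR was 49.4-fold higher, whereas ERBB4 was 52.9-fold lower and FGFR4 14.8-fold lower. Cholesterol synthesis genes had 12 of 25 up and 12 down (median 0.060, adjusted p = 0.242), hypoxia genes 15 of 25 up and 8 down (median 0.34, adjusted p = 0.0795) and markers of stroma and blood cells 4 of 9 down and 3 up (median -0.70, adjusted p = 0.831). Neural genes had 5 of 13 down and 2 up (median -0.88, or -0.15 at the bounds, adjusted p = 0.282) and RNAs without a poly(A) tail 10 of 19 up and 6 down (median 0.12, adjusted p = 0.70). Ranked first among the rises by fitted change were GPC6 (at least 515-fold), a cell surface proteoglycan, EYA4 (at least 313-fold), HMGA2 (at least 227-fold), PID1 (at least 205-fold) and ANKRD29 (at least 162-fold), all without counts in MCF7. Besides SUSD3, first among the falls were TENM3 (at least 1025-fold), ZFP3 (at least 240.2-fold), FGFBP2 (at least 230.3-fold) and NLRX1 (at least 209-fold), all without counts in TamR. In edgeR's quasi-likelihood test 11864 of 15942 genes passed, 2208 at least 2-fold higher and 2782 at least 2-fold lower. The largest adjusted p among the genes the naming rule gave was 4.77e-08, and the standard error of a log2 change given here as a plain fold was at most 0.171. Per the growth protocol TamR and MCF7 also differed in medium, serum and 4-hydroxytamoxifen, whereas a label of every library reads full media, so how far the comparison includes a change of culture is not settled.

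The other 2 sets of TamR and MCF7 libraries repeated many of these differences, but not those of luminal, p53 and cell cycle genes in the reference set. At least 2-fold in the same direction in all 3 sets, 1391 genes were higher and 1570 lower, where independent lists would share 44.7 and 76.6. CA12 was 426-fold lower with the scrambled shRNA and 185-fold lower in the reference set, FN1 239.7-fold higher and 1038-fold higher, CXCL8 275-fold higher and 1647-fold higher (95% counting interval 563 to 7992), and ISG15 96.3-fold lower and 55.5-fold lower. EYA4 again had no counts in MCF7 (at least 400.4-fold and at least 479.8-fold higher). GPC6 (at least 544-fold) and the transcription factor gene MEF2C (at least 849.7-fold) ranked first among the rises with the scrambled shRNA, and LDHB (7389-fold, interval 2528 to 35834), a lactate dehydrogenase subunit, in the reference set. Estrogen receptor targets fell, 26 of 38 down and 9 up (median -1.18, adjusted p = 4.78e-06) with the scrambled shRNA and 26 of 38 down and 9 up (median -1.61, adjusted p = 1.61e-07) in the reference set. Interferon genes fell in both, 37 of 38 down and 0 up (median -4.86, or -4.69 at the bounds, adjusted p = 2.19e-23) and 36 of 38 down and 2 up (median -3.70, adjusted p = 5.11e-20). AP-1 target genes rose, 24 of 36 up and 7 down (median 1.38, adjusted p = 4.99e-05) and 25 of 36 up and 5 down (median 1.65, adjusted p = 6.11e-06). Integrated stress response genes rose too, 25 of 30 up and 3 down (median 1.34, adjusted p = 3.67e-14) and 26 of 30 up and 4 down (median 1.85, adjusted p = 2.99e-15). PHGDH was 11.3-fold higher with the scrambled shRNA, and the asparagine synthetase ASNS 5.82-fold and 7.56-fold higher. Mesenchymal genes rose too, 18 of 30 up and 6 down (median 1.20, adjusted p = 0.00105) and 17 of 30 up and 5 down (median 0.89, adjusted p = 0.00138). Luminal genes fell with the scrambled shRNA, 25 of 36 down and 10 up (median -0.51, adjusted p = 6.49e-05), and gave no call in the reference set, 18 of 36 down and 18 up (median -0.016, adjusted p = 0.185) (adjusted p = 8.28e-07 for the difference from the first set, a rank test chosen after seeing the data). The p53 targets did likewise, 21 of 25 down and 4 up (median -0.89, adjusted p = 2.68e-05) and 13 of 25 down and 10 up (median -0.12, adjusted p = 0.399) (difference, adjusted p = 1.01e-09). Stem and progenitor genes gave no call with the scrambled shRNA, 12 of 23 up and 7 down (median 0.45, adjusted p = 0.0653), and rose in the reference set, 15 of 23 up and 4 down (median 0.98, adjusted p = 4.70e-04). The sets differed in cell cycle genes (adjusted p = 1.16e-19 for the first and last set, by the same test). These rose, 34 of 45 up and 7 down (median 0.43, adjusted p = 2.83e-04) with the scrambled shRNA, where RRM2 was 8.81-fold higher. They fell, 43 of 45 down and 1 up (median -1.05, adjusted p = 3.91e-16), in the reference set, where the proliferation marker MKI67 was 4.33-fold lower and the spindle factor TPX2 3.72-fold lower. RNAs without a poly(A) tail, mostly histones, stood at 14 of 19 up and 5 down (median 0.77, adjusted p = 0.00132) with the scrambled shRNA and 9 of 19 down and 0 up (median -1.08, adjusted p = 0.0684) in the reference set, which gave no call (difference from the first set, adjusted p = 0.00177). The tests called 12112 genes (2200 at least 2-fold higher, 2573 lower) with the scrambled shRNA and 11912 (2339 and 2721) in the reference set, with standard errors of the plain folds up to 0.0986 and 0.0927.

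Knocking down GATA3 in parental MCF7 asks what this luminal factor sustains. Interferon-induced genes rose in both experiments. With the stand-alone knockdown 37 of 38 measured members rose and 1 fell (median 1.31, adjusted p = 3.46e-36). The signal transducer STAT1 was 2.29-fold higher (1079 ± 4.87 against 470.4 ± 0.881 CPM), the RNA sensor DDX58 3.07-fold higher and IFI44L 12.9-fold higher. In the factorial experiment the rise was larger (difference, adjusted p = 1.20e-15), 38 of 38 up and 0 down (median 2.84, adjusted p = 2.02e-59). DDX58 was 6.93-fold higher, IFI44L 24.4-fold higher and IFIT2 26.3-fold higher (547 ± 13.2 against 20.7 ± 1.56 CPM). Luminal genes fell in the first, 22 of 36 down and 11 up (median -0.52, adjusted p = 1.47e-08), but had no set-level call in the factorial experiment, 16 of 36 down and 17 up (median -0.015, adjusted p = 0.132) (difference, adjusted p = 4.31e-06). The cell adhesion protein CDH1 was 4.33-fold lower in the stand-alone experiment, CRABP2 10.7-fold lower and 8.94-fold lower, the simple-epithelium keratin KRT18 2.53-fold lower and 2.27-fold lower, and BCL2 6.18-fold lower in the factorial experiment. Basal genes rose in both, 17 of 29 up and 5 down (median 0.83, adjusted p = 0.0145) and 19 of 29 up and 2 down (median 0.97, adjusted p = 3.88e-04). GABRP was 4.04-fold and 8.80-fold higher and the basal keratin KRT17 5.38-fold higher in the second.

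Individual estrogen receptor targets were lower after GATA3 knockdown. PGR, the progesterone receptor, was 2.71-fold and 2.5-fold lower, and CA12 2.61-fold and 2.77-fold lower. As a set the list had no call in the stand-alone experiment, 18 of 38 down and 16 up (median -0.050, adjusted p = 0.181), and fell in the factorial one, 26 of 38 down and 9 up (median -0.49, adjusted p = 1.19e-06). ESR1 was 2.06-fold and 1.38-fold lower, and JUN 1.33-fold higher and then 1.54-fold lower. Cholesterol synthesis genes rose in the first experiment, 22 of 25 up and 1 down (median 0.64, adjusted p = 8.02e-10), among them INSIG1 (4.15-fold), the low density lipoprotein receptor LDLR (3.15-fold) and STARD4 (5.32-fold). They gave no set-level call in the factorial one, 13 of 25 down and 6 up (median -0.12, adjusted p = 0.112, 6 up and 14 down adjusted over the list alone). Cell cycle genes gave none in the first, 23 of 45 down and 14 up (median -0.13, adjusted p = 0.0736, 16 up and 24 down adjusted over the list alone). They fell in the factorial experiment, 44 of 45 down and 1 up (median -0.97, adjusted p = 5.73e-30). TOP2A was 2.34-fold lower and RRM2 3.16-fold lower. NF-kB genes rose in the factorial experiment, 19 of 23 up and 0 down (median 1.75, adjusted p = 1.39e-07, 20 up and 0 down adjusted over the list alone). The feedback inhibitor TNFAIP3 was 15.9-fold higher and complement factor CFB 18.4-fold higher. The p53 targets rose as well, 20 of 25 up and 4 down (median 0.48, adjusted p = 2.03e-05). TP53INP1 was 3.91-fold higher. AP-1 family members rose in that experiment, 13 of 19 up and 2 down (median 0.55, or 0.38 at the bounds, adjusted p = 0.0470, and adjusted p = 0.140 with an estimated correlation), a call also lost with RLE size factors and in a fit of those groups alone (adjusted p = 0.0512 and 0.0531). The transcriptional inhibitor ID1 was 6.64-fold and 4.26-fold higher, and the hepatocyte growth factor receptor MET 2.03-fold higher in the first.

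Among the rises ranked first by fitted change, FGG, a fibrinogen chain, was 371-fold higher (95% counting interval 102 to 3069) and at least 188-fold higher, and others were DCLK2 (127-fold) in the stand-alone experiment and UGT2B10 (at least 196-fold), CXCL17 (124-fold) and the copper carrier CP (111-fold) in the factorial one. The decoy receptor TNFRSF11B (42.0-fold and 53.7-fold) and AFAP1L2 (59.2-fold and 39.4-fold) were among the falls ranked first in both. Others were RHBG (85.6-fold), CHRD (76.2-fold), a bone morphogenetic protein antagonist, and SLC5A8 (46.7-fold) in the first, and STC1 (62.2-fold) and PDZK1 (28.2-fold) in the second. The stand-alone knockdown changed 9788 genes, 1323 at least 2-fold up and 946 down, and the factorial one 9816, 1448 up and 983 down. At least 2-fold in the same direction in both experiments were 751 rises and 444 falls, against 120.2 and 58.3 for independent lists. The largest adjusted p among the genes of the naming rule that passed was 0.0483 and 8.55e-04 in edgeR, and standard errors of the plain folds reached 0.298 and 0.306. The labels name a single shRNA against GATA3 and state puromycin selection only for the knockdown, so neither off-target effects of the shRNA nor the selection are separated from the loss of GATA3.

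Inducing JUN in MCF7 asks what raised AP-1 activity does to a luminal cell. Basal, mesenchymal, AP-1 target and NF-kB genes rose as lists in both experiments. The laminin-332 chains LAMA3 and LAMB3 were 21.4-fold and 25.1-fold higher in the stand-alone experiment. In the factorial one they were 24.0-fold and 65.1-fold higher, and the partner chain LAMC2 88.2-fold. Integrin ITGB6 was 21.6-fold higher (609 ± 4.65 against 28.1 ± 2.32 CPM) and 43.8-fold higher, and ITGAV 5.59-fold and 8.70-fold higher. The matrix protein TGFBI was 152-fold and 309.5-fold higher, lysyl oxidase LOXL2 16.9-fold and 17.2-fold higher, and FN1 12-fold higher in the first. Basal genes rose, 21 of 29 up and 3 down (median 1.54, adjusted p = 6.28e-09, 22 up and 3 down adjusted over the list alone) and 22 of 29 up and 2 down (median 1.32, adjusted p = 1.28e-08). Mesenchymal genes rose too, 18 of 30 up and 1 down (median 1.07, adjusted p = 1.03e-09) and 16 of 30 up and 2 down (median 1.08, adjusted p = 2.07e-06). AP-1 target genes rose, 27 of 36 up and 1 down (median 1.60, or 1.28 at the bounds, adjusted p = 4.93e-10) and 26 of 36 up and 1 down (median 1.61, adjusted p = 1.44e-08). The plasminogen activator inhibitor SERPINE1 was 8.59-fold and 32.4-fold higher and the urokinase receptor PLAUR 25.2-fold and 50.3-fold higher. The cytokine LIF was 8.36-fold and 13.9-fold higher.

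NF-kB genes rose with JUN, 20 of 23 up and 0 down (median 3.06, or 2.65 at the bounds, adjusted p = 3.54e-12) and 21 of 23 up and 1 down (median 3.50, or 2.97 at the bounds, adjusted p = 4.93e-10). The adhesion receptor ICAM1 was 17.8-fold and 31.5-fold higher. Interferon genes rose, 36 of 38 up and 0 down (median 1.92, adjusted p = 6.51e-32) and 37 of 38 up and 0 down (median 1.10, adjusted p = 5.11e-20). STAT1 was 2.83-fold and 1.67-fold higher, DDX60 4.86-fold higher in the first and ISG20 9.09-fold higher in the second. Hypoxia genes rose, 23 of 25 up and 1 down (median 1.28, adjusted p = 4.09e-12) and 20 of 25 up and 3 down (median 0.64, adjusted p = 6.11e-06). The disulfide-forming oxidase ERO1A was 3.82-fold and 1.93-fold higher, and the angiogenic factor VEGFA 4.15-fold higher in the second. Stem and progenitor genes rose, 12 of 23 up and 6 down (median 0.66, or 0.47 at the bounds, adjusted p = 0.0122) and 15 of 23 up and 3 down (median 0.61, or 0.47 at the bounds, adjusted p = 5.35e-04), among them the transcription factor SOX9 (21.2-fold and 41.3-fold) and the retinaldehyde dehydrogenase ALDH1A3 (19.1-fold and 42.9-fold). Receptor tyrosine kinases and ligands rose, 14 of 30 up and 5 down (median 0.66, adjusted p = 0.0448), a call lost in a fit of those groups alone (adjusted p = 0.0889), and 16 of 30 up and 7 down (median 0.33, adjusted p = 0.0110), and AP-1 family members did in the factorial experiment, 12 of 19 up and 4 down (median 1.23, or 0.60 at the bounds, adjusted p = 0.00651, and adjusted p = 0.0643 with an estimated correlation). The AP-1 family list holds the induced JUN, and without JUN its set test gave adjusted p = 0.0383, or 0.135 with an estimated correlation.

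The experiments differed in estrogen receptor targets and cell cycle genes (adjusted p = 1.49e-07 and 1.70e-18), and in integrated stress response, p53 and cholesterol genes (adjusted p = 2.05e-11, 8.04e-09 and 1.38e-08), by the rank test of the difference. ESR1 was 1.15-fold higher in the first and 3.04-fold lower in the factorial experiment, and GATA3 1.17-fold lower and 2.0-fold lower. The uninduced controls already differed in ESR1, at 178 ± 5.16 CPM in the first and 504 ± 10.7 in the factorial experiment. The induced groups lay closer, at 205 ± 6.90 and 166 ± 2.67 CPM, so the 2 ESR1 responses started from unlike levels. Estrogen receptor targets gave no set-level call in the first, 16 of 38 up and 11 down (median 0.0059, adjusted p = 0.162). They fell in the second, 29 of 38 down and 6 up (median -0.60, adjusted p = 2.50e-09), where PGR was 3.45-fold lower, the coactivator GREB1 3.18-fold lower and GFRA1 3.77-fold lower. Cell cycle genes fell in both, 24 of 45 down and 17 up (median -0.24, adjusted p = 0.0444, and adjusted p = 0.103 with an estimated correlation) and 44 of 45 down and 1 up (median -1.86, adjusted p = 1.26e-44). TOP2A was 2.21-fold and 4.07-fold lower and MKI67 1.75-fold and 3.81-fold lower. Integrated stress response genes fell in the first, 23 of 30 down and 3 up (median -0.93, adjusted p = 4.30e-14). AARS was 2.6-fold lower, ASNS 2.53-fold lower and SLC7A11 3.85-fold lower. They rose in the second, 20 of 30 up and 7 down (median 0.37, adjusted p = 2.53e-04). The p53 targets fell in the first, 21 of 25 down and 4 up (median -1.01, adjusted p = 2.89e-09). MDM2 was 2.38-fold lower and CCNG1 2.63-fold lower. They gave no call in the second, 11 of 25 up and 8 down (median 0.10, adjusted p = 0.234, 13 up and 9 down adjusted over the list alone). Cholesterol synthesis genes rose in the first, 22 of 25 up and 1 down (median 0.86, adjusted p = 7.07e-10). LDLR was 6.57-fold higher and INSIG1 4.07-fold higher. They gave no call in the second, 16 of 25 down and 7 up (median -0.24, adjusted p = 0.0795, 8 up and 16 down adjusted over the list alone). RNAs without a poly(A) tail fell in the first, 18 of 19 down and 1 up (median -0.62, adjusted p = 3.44e-11). In the second 4 were up and 4 down (median 0.34, 3 up and 4 down adjusted over the list alone). For this list the difference between the experiments did not pass (adjusted p = 0.0634 by the same rank test).

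Among the rises ranked first by fitted change were UBD (at least 96.3-fold), CST5 (at least 85.6-fold), ALPK2 (339-fold, interval 60.5 to 13441) and the matrix protein ECM1 (136-fold) in the first experiment, and SPRR1B (at least 136-fold), a cornified envelope protein, CST5 (at least 127-fold), the vascular cadherin CDH5 (at least 118-fold) and CEACAM5 (677-fold) in the second. First among the falls were TGM1 (15.3-fold), the desmosomal protein PKP1 (12.8-fold) and CLGN (12.6-fold), and in the second PCDH19 (15.2-fold), TNFRSF11B (11.7-fold) and TEX14 (11-fold). The tests called 10341 genes (1816 at least 2-fold up, 846 down) and 9926 (1663 and 1031). Both experiments shared 994 rises and 192 falls of at least 2-fold, against 189 and 54.7 for independent lists. The largest adjusted p among the genes the naming rule gave was 2.88e-04 and 6.27e-04 in edgeR, and standard errors of the plain folds reached 0.201 and 0.189. No library received doxycycline without the JUN cassette, so the drug and the induced gene are not separated.

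The combination of GATA3 knockdown and JUN induction in MCF7 asks whether the joint change moves the parental cell toward the TamR state. It lowered GATA3 9.85-fold and ESR1 4.50-fold. PGR was 10.6-fold lower (51.0 ± 4.31 against 540.1 ± 11.8 CPM), BCL2 19.0-fold lower, CA12 3.84-fold lower and GREB1 3.31-fold lower. Estrogen receptor targets fell, 29 of 38 down and 7 up (median -0.64, adjusted p = 1.43e-08). Luminal genes, BCL2 among them, gave no set-level call, 18 down and 16 up (adjusted p = 0.0663, 16 up and 20 down adjusted over the list alone). Laminins LAMC2 and LAMB3 were 121-fold higher and 70.1-fold higher, the fibronectin receptor subunit ITGA5 48.5-fold higher (304 ± 2.46 against 6.29 ± 0.623 CPM) and LOXL2 33.1-fold higher. Basal, mesenchymal and AP-1 target genes rose, 23 of 29 up and 1 down (median 1.87, adjusted p = 1.28e-07, 24 up and 1 down adjusted over the list alone), 22 of 30 up and 3 down (median 1.70, adjusted p = 8.48e-07) and 29 of 36 up and 5 down (median 2.34, adjusted p = 7.80e-09) respectively, with SERPINE1 69.8-fold higher and PLAUR 59.9-fold higher. So did AP-1 family members, 14 of 19 up and 3 down (median 1.43, or 1.37 at the bounds, adjusted p = 1.01e-04, and adjusted p = 7.0e-04 without JUN in the list). The stress-induced factor ATF3 was 21.9-fold higher. Interferon genes rose, 38 of 38 up and 0 down (median 2.90, adjusted p = 2.17e-36). IFIT2 was 23.2-fold higher, DDX58 6.81-fold higher and ISG15 4.05-fold higher. NF-kB genes rose too, 21 of 23 up and 0 down (median 3.42, adjusted p = 1.06e-08). TNFAIP3 was 23.4-fold higher. Cell cycle genes fell, 44 of 45 down and 1 up (median -2.0, adjusted p = 5.39e-33). MKI67 was 4.37-fold lower and TOP2A 6.88-fold lower. Hypoxia genes rose, 21 of 25 up and 3 down (median 1.45, adjusted p = 2.16e-08), among them ERO1A (4.10-fold) and the lipase inhibitor ANGPTL4 (42.9-fold). Stem and progenitor genes rose, 14 of 23 up and 3 down (median 0.89, or 0.77 at the bounds, adjusted p = 5.35e-04). SOX9 was 81.8-fold higher.

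Ranked first by fitted change with both changes were the rises of CEACAM5 (1370.3-fold), FGG (at least 309-fold), SPRR1B (at least 207-fold), CDH5 (at least 202-fold) and SCEL (551-fold, interval 98.5 to 21819), and the falls of PDZK1 (78.6-fold), RBM24 (52.0-fold), KCNK5 (46.6-fold), PCDH19 (33.8-fold) and TNFRSF11B (27.9-fold). In all 11087 genes passed in edgeR, 2285 at least 2-fold higher and 1558 lower, with a largest adjusted p among the rule's genes of 2.54e-08 and standard errors of the plain folds up to 0.229. Of the genes at least 2-fold higher in TamR than in MCF7, 763 were also at least 2-fold higher with both changes, where independent lists would share 316, and 162 were lower, against 216. Of those lower in TamR, 580 fell and 388 rose, against 272 and 399. Over all calls the shared numbers were 2648 higher and 2719 lower, against 2002 and 2124, with 1798 and 1738 genes in opposite directions. The overlap had p = 1.92e-109 for rises and p = 3.05e-91 for falls in Fisher's exact test (2-sided), which treats genes as independent although they are not. The 2 comparisons share no library, and 11 such pairs of comparisons were computed.

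Whether the 2 changes acted independently was asked with the interaction, the response to JUN with GATA3 knocked down minus the response without, on the log2 scale with its SE. Interferon and NF-kB genes responded less than additively in MCF7. Of the interferon genes, 34 of 38 negative and 0 positive (median -1.15, adjusted p = 1.86e-59) had an interaction that passed, among them STAT1 (-0.80 ± 0.030), UBE2L6 (-1.83 ± 0.060) and PARP14 (-1.21 ± 0.040), and of the NF-kB genes 17 of 23 negative and 0 positive (median -2.37, adjusted p = 2.27e-13), with TNFAIP3 (-2.70 ± 0.150) and CFB (-3.07 ± 0.194). Basal genes were below additive too, 15 of 29 negative and 1 positive (median -0.64, adjusted p = 2.91e-04), with GABRP (-4.42 ± 0.137). Cell cycle genes were above the sum of the 2 falls, 43 of 45 positive and 0 negative (median 0.75, adjusted p = 1.64e-31), with RRM2 (1.21 ± 0.070) and MCM7 (0.80 ± 0.039). The transcript of JUN (1.22 ± 0.046) itself lay above additive. Other strong interactions were BCAS1 (-4.23 ± 0.043), CEACAM6 (-3.98 ± 0.096), MAP1B (-3.82 ± 0.083), LXN (-2.43 ± 0.047) and STC2 (2.13 ± 0.065), and the small GTPase RHOB (1.74 ± 0.038). In edgeR 5616 genes passed, 334 with an interaction of at least 1 log2 unit upward and 630 downward, and the largest adjusted p among the rule's genes that passed was 0.0153.

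Knocking down JUN in TamR asks whether the resistant state depends on this AP-1 subunit. AP-1 target, mesenchymal and basal genes fell as lists. FN1 went from 3537 ± 7.72 to 37.8 ± 3.55 CPM (94.0-fold lower), CXCL8 was 151-fold lower, ITGB6 68.5-fold lower, LOX 10.7-fold lower, the collagen COL1A1 10.5-fold lower and the cadherin CDH3 11.1-fold lower. Of the AP-1 target genes 32 of 36 measured members fell and 1 rose (median -3.13, or -2.58 at the bounds, adjusted p = 2.02e-08). PHLDA1 was 42.1-fold lower, DUSP6 23.7-fold lower and the ERK pathway inhibitor SPRY4 17.2-fold lower. Mesenchymal genes fell, 21 of 30 down and 5 up (median -1.58, adjusted p = 3.75e-04, 6 up and 21 down adjusted over the list alone). Basal genes fell, 21 of 29 down and 3 up (median -2.09, or -1.60 at the bounds, adjusted p = 0.00335), and stem and progenitor genes fell, 18 of 23 down and 2 up (median -2.20, adjusted p = 8.57e-06). The proto-oncogene MYC was 36.0-fold lower, the surface protein CD24 16.2-fold lower and SOX4 7.13-fold lower. Receptor tyrosine kinases and ligands fell, 23 of 30 down and 4 up (median -1.18, adjusted p = 1.97e-04), as did the AP-1 family, 12 of 19 down and 3 up (median -1.22, adjusted p = 0.0373, and adjusted p = 0.146 with an estimated correlation), but this list holds JUN itself and its call was lost without it (adjusted p = 0.0743).

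Luminal genes and estrogen receptor targets were lower with JUN knockdown too. ESR1 was 9.91-fold lower (34.5 ± 1.11 against 341 ± 5.53 CPM), GATA3 2.09-fold lower, KRT18 5.37-fold lower and AGR2 18.2-fold lower. Estrogen receptor targets fell, 30 of 38 down and 2 up (median -1.71, or -1.39 at the bounds, adjusted p = 1.28e-08). Cyclin CCND1 was 11.7-fold lower, CELSR2 8.05-fold lower and the retinoic acid receptor RARA 13.4-fold lower. Luminal genes fell, 29 of 36 down and 5 up (median -1.30, adjusted p = 2.16e-08). Integrated stress response genes fell, 24 of 30 down and 4 up (median -1.98, adjusted p = 4.30e-14). DDIT4 was 42.0-fold lower, the gluconeogenic enzyme PCK2 10.3-fold lower and ASNS 4.20-fold lower. Cell cycle genes fell, 42 of 45 down and 1 up (median -1.59, adjusted p = 3.91e-16, 2 up and 42 down adjusted over the list alone). TOP2A was 4.86-fold lower and MKI67 4.13-fold lower. Hypoxia genes fell, 15 of 25 down and 5 up (median -1.09, adjusted p = 0.00394, and adjusted p = 0.0635 with an estimated correlation). Interferon genes gave no set-level call, 14 of 38 up and 8 down (median 0.35, or 0.24 at the bounds, adjusted p = 0.232, 13 up and 8 down adjusted over the list alone), although IFI6 was 32.6-fold higher. Cholesterol synthesis genes rose slightly, 16 of 25 up and 7 down (median 0.38, adjusted p = 0.0465, and adjusted p = 0.0813 with an estimated correlation). RNAs without a poly(A) tail fell with these lists, 16 of 19 down and 0 up (median -1.67, adjusted p = 4.93e-10), among them histones HIST1H1D (10.8-fold) and HIST1H3B (6.79-fold). The nuclear RNAs MALAT1 and NEAT1 were 9.70-fold and 20.8-fold lower, while RMRP, RPPH1 and SCARNA2 did not pass (adjusted p = 0.0774, 0.262 and 0.431). As CPM of the total, MALAT1 stood at 1686 ± 4.79 against 14585.5 ± 44.1 in the control. In the reference TamR libraries, which hold little small RNA, it was 1263 ± 21.0. A difference in RNA preparation between the 2 groups was not tested and is not separated from the loss of JUN.

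Ranked first by fitted change with JUN knockdown were the falls of S100A14 (205-fold), FOLR1 (222-fold, interval 61.0 to 1839), the stress regulator NUPR1 (185-fold), CXCL8 and PKP1 (138-fold), and the rises of SYT11 (705-fold, interval 126 to 27877), ILDR2 (37.2-fold), IFI6, the orphan nuclear receptor NR4A3 (24.2-fold) and RCAN2 (23.6-fold). In edgeR 11973 genes passed, 1740 at least 2-fold higher and 3297 lower, the largest adjusted p among the rule's genes was 4.90e-04, and standard errors of the plain folds reached 0.279. Of the 2208 genes at least 2-fold higher in TamR than in MCF7, 993 were at least 2-fold lower after JUN knockdown, against 457 for independent lists, and 187 were higher, against 241. Of the 2782 genes lower in TamR, 387 rose, against 304, and 577 fell further, against 575. The knockdown has no repeat in other libraries, the labels name a single shRNA, and puromycin selection of its control is not stated.

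T47D carried the same factorial design and asks whether the responses hold in a second luminal line. The combined change raised interferon-induced genes by more than in MCF7 (adjusted p = 1.62e-17 by the rank test of the difference between lines, chosen after seeing the data). Of the interferon genes, 38 of 38 measured members rose and 0 fell (median 5.80, adjusted p = 2.58e-297), with IFIT1 at 1340.0 ± 8.2 against 8.39 ± 0.410 CPM (159.7-fold higher), IFIT3 331-fold higher and STAT1 11.4-fold higher. IFNB1, which encodes interferon beta, had no counts in the control and was at least 83.5-fold higher, the interferon-induced chemokines CXCL10 and CXCL11 were 860.4-fold higher (95% counting interval 154 to 34019) and at least 142-fold higher, and the nucleic acid sensor ZBP1 was at least 149-fold higher. JUN alone also raised the list, 38 of 38 up and 0 down (median 2.32, adjusted p = 9.58e-64). IFIT1 was 15.6-fold higher, IFI6 9.21-fold higher and STAT1 2.86-fold higher. GATA3 knockdown alone raised it too, 35 of 38 up and 2 down (median 1.34, adjusted p = 1.03e-17). IFIT1 was 6.32-fold higher, SAMD9 6.88-fold higher and STAT1 1.79-fold higher. The interaction was positive for the list, 36 of 38 positive and 1 negative (median 2.06, adjusted p = 7.90e-35), with IFIH1 (2.99 ± 0.080), an RNA sensor, STAT1 (1.16 ± 0.031) and STAT2 (2.04 ± 0.062). NF-kB genes gave no set-level call with JUN alone, 9 of 23 up and 4 down (median 0.69, or 0 at the bounds, adjusted p = 0.470), nor with GATA3 knockdown alone, 5 of 23 up and 5 down (median 0.16, or 0 at the bounds, adjusted p = 0.699). They rose with both, 20 of 23 up and 1 down (median 4.02, adjusted p = 1.12e-07, and adjusted p = 0.0544 with an estimated correlation), with CFB (109-fold), TNFAIP3 (24.7-fold) and NFKBIA (4.44-fold). Their interaction was positive too, 17 of 23 positive and 0 negative (median 3.43, adjusted p = 1.25e-07), with TNFAIP3 (3.87 ± 0.291) and NFKB1 (1.33 ± 0.087).

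**Figure D2:**
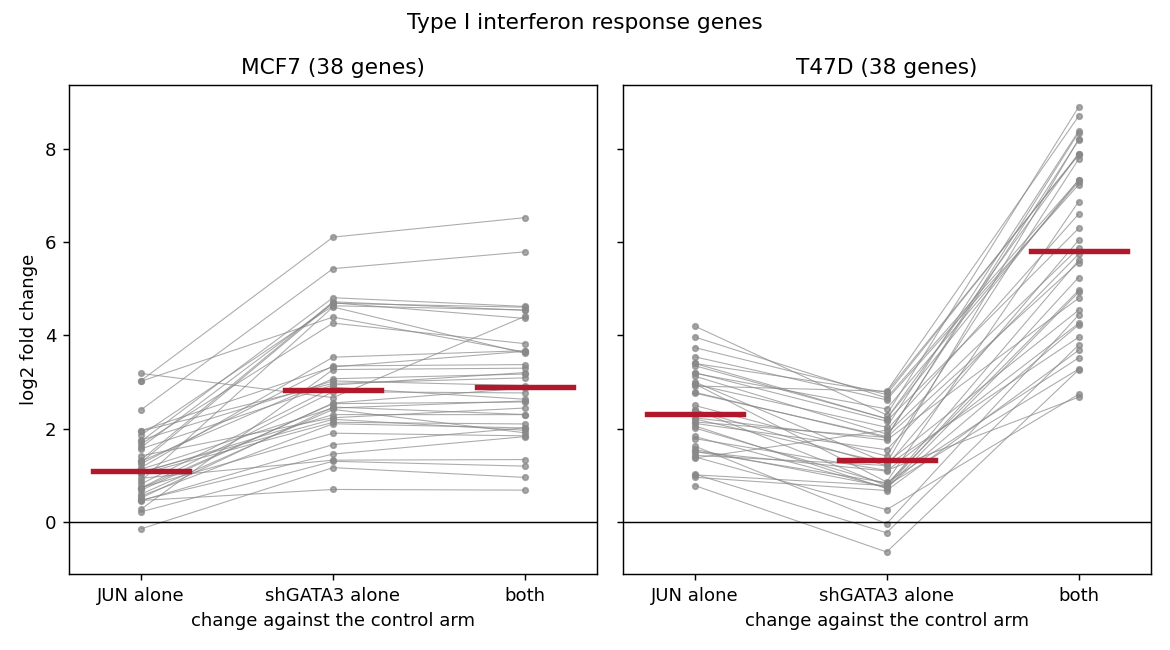
Log2 fold change of the 38 genes of the type I interferon list for JUN alone, GATA3 knockdown alone and both, in MCF7 and T47D. Each dot is a gene and red bars are medians. With both changes the median is 2.90 in MCF7 and 5.80 in T47D.

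Basal, mesenchymal and AP-1 target genes rose in T47D with JUN as they had in MCF7. KRT17 was 49.7-fold higher with JUN alone and 215-fold higher with both (151 ± 1.52 against 0.693 ± 0.179 CPM). In that order LAMB3 was 40.7-fold and 66.6-fold higher, TGFBI 44.8-fold and 98.0-fold, and ITGA5 7.43-fold and 33.6-fold. LAMC2 was 23.1-fold and LIF 8.07-fold higher with JUN alone. Basal genes rose, 18 of 25 up and 0 down (median 1.11, adjusted p = 9.21e-14) and 17 of 25 up and 3 down (median 1.44, adjusted p = 1.49e-06). Mesenchymal genes rose too, 16 of 27 up and 3 down (median 0.76, adjusted p = 3.71e-07, 17 up and 3 down adjusted over the list alone) and 17 of 27 up and 3 down (median 1.31, adjusted p = 2.30e-06). AP-1 target genes rose, 17 of 31 up and 2 down (median 1.00, or 0.85 at the bounds, adjusted p = 1.08e-05) and 23 of 31 up and 4 down (median 2.11, adjusted p = 2.89e-05). GATA3 knockdown alone gave no call for basal genes, 8 of 25 up and 4 down (median 0.042, adjusted p = 0.423), or AP-1 target genes, 7 of 31 up and 7 down (median 0.0017, adjusted p = 0.668). AP-1 family members rose with both, 13 of 18 up and 4 down (median 1.00, adjusted p = 1.25e-07, and adjusted p = 0.0544 with an estimated correlation, 13 up and 5 down adjusted over the list alone), with BATF2 (354-fold) and ATF3 (12.5-fold). That list holds the induced JUN, and without JUN the set test gave adjusted p = 0.00418, or 0.167 with an estimated correlation. ESR1 was 2.37-fold lower with JUN, 1.11-fold higher with GATA3 knockdown and 2.86-fold lower with both. PGR was 2.11-fold lower with GATA3 knockdown and 10.9-fold lower with both, CA12 2.14-fold lower, 2.43-fold lower and 5.46-fold lower in the same order, and the secreted peptide TFF1 1.62-fold lower with JUN. Estrogen receptor targets fell with JUN, 29 of 36 down and 5 up (median -0.79, adjusted p = 1.85e-18). They also fell with both, 28 of 36 down and 4 up (median -0.66, adjusted p = 6.43e-08, and adjusted p = 0.0705 with an estimated correlation). The luminal list had 16 of 37 down and 14 up (median -0.10, adjusted p = 0.0418, and adjusted p = 0.115 with an estimated correlation, 14 up and 17 down adjusted over the list alone) with GATA3 knockdown, a call lost when GATA3 itself was left out of the list (adjusted p = 0.260). Its members CDH1 and CRABP2 were 2.77-fold and 6.64-fold lower.

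Cell cycle genes fell in each arm in T47D. The list had 43 of 45 down and 0 up (median -1.67, adjusted p = 1.42e-81) with JUN, 44 of 45 down and 0 up (median -1.16, adjusted p = 1.25e-49) with GATA3 knockdown and 43 of 45 down and 0 up (median -2.51, adjusted p = 3.87e-44) with both. TOP2A was 3.97-fold, 3.19-fold and 13.2-fold lower in that order, MKI67 3.58-fold and 8.09-fold lower with JUN and both, RRM2 3.16-fold lower with GATA3 knockdown, and the mitotic kinesin KIF20A 4.80-fold and 23.7-fold lower with GATA3 knockdown and both. Cholesterol synthesis genes fell with GATA3 knockdown, 18 of 25 down and 3 up (median -0.30, adjusted p = 2.71e-06). SREBF2 was 2.18-fold lower and HMGCS1 1.55-fold lower. Integrated stress response genes were above additive, 24 of 30 positive and 1 negative (median 0.65, adjusted p = 2.13e-24, 25 up and 1 down adjusted over the list alone), with STC2 (2.94 ± 0.067), WARS (2.15 ± 0.042) and ASNS (1.12 ± 0.059). The transcript of JUN (0.99 ± 0.119) was above additive, as in MCF7. Other interactions were HSPA5 (0.75 ± 0.00661) and HSP90B1 (0.62 ± 0.00906), chaperones of the endoplasmic reticulum, the elongation factor EEF2 (-0.70 ± 0.00301) and SPTSSB (1.80 ± 0.036). Among the rises ranked first by fitted change were KRT16 (219-fold, interval 60.3 to 1816), GABRP (231-fold, interval 41.0 to 9170.1), SPRR1B (158-fold, interval 43.3 to 1309.7) and S100P (122-fold) with JUN, CXCL17 (10.4-fold), the neural transcription factor ASCL1 (5.69-fold) and VWF (5.50-fold) with GATA3 knockdown, and the collagenase MMP13 (at least 174-fold) with both. Falls ranked first included NXPH3 (5.13-fold), PTTG1 (4.84-fold) and PBK (4.70-fold) with JUN, KCNK5 (16.0-fold), SHISA2 (14.6-fold) and MALRD1 (11.6-fold) with GATA3 knockdown, and MALRD1 (45.5-fold), NEIL3 (19.7-fold) and the prolactin-induced protein PIP (19.3-fold) with both. JUN changed 6842 genes in edgeR (709 at least 2-fold up, 492 down), GATA3 knockdown 8057 (382 and 832) and both 10111 (1466 and 1392), and 5806 had an interaction. The largest adjusted p among the rule's genes that passed was 0.0160, 0.00170, 2.20e-05 and 0.00642, and standard errors of the plain folds reached 0.216, 0.246 and 0.274. The combined change gave 1127 rises and 858 falls of at least 2-fold in both lines, against 198 and 129 for independent lists. With DESeq2 the interaction in T47D counted 3685 genes.

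The xenograft that grew under estrogen deprivation, set against the same model with estrogen, asks which genes accompany hormone-independent growth. Estrogen receptor targets were lower. Of the list, 32 of 37 measured members fell and 4 rose (median -1.21, adjusted p = 1.58e-21, and adjusted p = 0.208 with an estimated correlation). CXCL12 was 17.3-fold lower, GFRA1 13.8-fold lower (58.8 ± 1.80 against 810.2 ± 1.04 CPM) and CELSR2 2.71-fold lower. ESR1, GATA3 and JUN were all higher in the deprived tumour, at 723 ± 0.853 against 465 ± 5.45 CPM, 861 ± 1.70 against 504 ± 9.83 CPM and 204 ± 0.234 against 69.2 ± 1.00 CPM. Interferon genes were lower, 30 of 38 down and 2 up (median -1.15, adjusted p = 3.61e-15, and adjusted p = 0.206 with an estimated correlation, 2 up and 31 down adjusted over the list alone). IFI27 was 7.26-fold lower, IFIT1 5.02-fold lower, IFI6 3.76-fold lower and STAT1 2.28-fold lower. Mesenchymal genes were higher, 33 of 39 up and 3 down (median 0.87, adjusted p = 2.19e-13, and adjusted p = 0.206 with an estimated correlation, 34 up and 3 down adjusted over the list alone). FN1 was 2.35-fold higher. Markers of stroma and blood cells were higher beside them, 17 of 20 up and 0 down (median 0.93, adjusted p = 7.51e-08, and adjusted p = 0.206 with an estimated correlation, 17 up and 1 down adjusted over the list alone), with the collagens COL3A1 (1.85-fold) and COL1A2 (1.63-fold), which the mesenchymal list also holds, and the endothelial protein VWF (5.58-fold). Basal genes were higher, 16 of 24 up and 3 down (median 0.71, adjusted p = 0.00732, and adjusted p = 0.212 with an estimated correlation). Neural genes were higher too, 9 of 13 up and 1 down (median 0.43, adjusted p = 4.83e-04, and adjusted p = 0.233 with an estimated correlation). ASCL1 was 41.4-fold higher, the granule protein CHGA 2.16-fold higher and the vesicle protein SYT1 2.40-fold higher, while TUBB3 was 1.65-fold lower. Cell cycle genes were lower, 36 of 45 down and 0 up (median -0.26, adjusted p = 7.51e-08, and adjusted p = 0.206 with an estimated correlation). MKI67 was 1.78-fold lower and MYBL2 2.12-fold lower. Hypoxia genes were lower, 13 of 24 down and 6 up (median -0.29, adjusted p = 0.00301, and adjusted p = 0.208 with an estimated correlation). P4HA1 was 2.79-fold lower and LDHA 1.76-fold lower. AP-1 target genes gave no set-level call, 13 of 31 up and 10 down (median 0.32, adjusted p = 0.377), nor did luminal genes, 20 of 38 down and 15 up (median -0.096, adjusted p = 0.0990), although the mucin MUC1 was 24.0-fold higher.

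Ranked first by fitted change in the deprived xenograft were the rises of the cannabinoid receptor CNR1 (at least 230.3-fold), KIR3DL1 (at least 171-fold), KIR3DL2 (790.2-fold), ALB (339-fold) and ASXL3 (274-fold). The KIR genes are near-identical members of a family whose reads can be shared, so their values are uncertain. First among the falls were SERTM1 (at least 197-fold), OTOS (1364-fold, interval 467 to 6619), SPOCD1 (353-fold, interval 97.4 to 2921), UBE2QL1 (118-fold) and the neuropeptide receptor NPY1R (118-fold). In edgeR 9346 of 14827 genes passed, 1412 at least 2-fold higher and 617 lower, with a largest adjusted p among the rule's genes of 5.53e-05 and standard errors of the plain folds up to 0.248, and DESeq2 called 6104. None of the list calls in the xenograft holds with an estimated correlation, in a fit with 2 residual degrees of freedom, and mouse reads counted as human were not assessed.

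To follow the TamR state through the other libraries, the 200 genes with the smallest p among those at least 2-fold higher in TamR than in MCF7, and the 200 among those lower, were tested in comparisons that share no library with that one. The combined change in MCF7 moved both lists toward TamR. The genes high in TamR rose, 156 of 200 up and 25 down (median 1.12, adjusted p = 1.57e-24). Those low in TamR fell, 142 of 200 down and 49 up (median -0.67, adjusted p = 3.34e-15). Not every gene list moved that way. Interferon genes, lower in TamR, rose with both changes, and cell cycle genes, higher in the first TamR set, fell. The high list also rose with GATA3 knockdown, 134 of 200 up and 47 down (median 0.48, adjusted p = 7.12e-14) and 132 of 200 up and 37 down (median 0.52, adjusted p = 8.65e-15) in the stand-alone and factorial experiments, and with JUN, 145 of 200 up and 35 down (median 0.87, adjusted p = 8.35e-21) and 149 of 200 up and 27 down (median 0.88, adjusted p = 2.22e-25). The low list fell with GATA3 knockdown, 154 of 200 down and 35 up (median -0.75, adjusted p = 3.67e-39) and 128 of 200 down and 51 up (median -0.51, adjusted p = 5.22e-16), and with JUN, 103 of 200 down and 75 up (median -0.14, adjusted p = 0.00957, and adjusted p = 0.0649 with an estimated correlation) and 134 of 200 down and 50 up (median -0.40, adjusted p = 1.28e-12). Both changes exceeded JUN alone by a median of 0.18 for the high list and -0.28 for the low list, and exceeded GATA3 knockdown alone by 0.54 and -0.20. In T47D with both changes the high list rose, 134 of 198 up and 34 down (median 0.59, adjusted p = 1.61e-10). The low list fell, 129 of 196 down and 55 up (median -0.43, adjusted p = 4.26e-11). JUN knockdown in TamR turned the high list down, 179 of 200 down and 18 up (median -1.76, adjusted p = 4.94e-45), and lowered the low list too, 121 of 200 down and 47 up (median -0.88, adjusted p = 3.80e-05). In the xenograft the high list gave no call, 82 of 189 up and 73 down (median 0.050, adjusted p = 0.630), and the low list fell, 106 of 185 down and 61 up (median -0.18, adjusted p = 6.43e-05, and adjusted p = 0.0649 with an estimated correlation). In the 2 repeats of TamR against MCF7, 199 and 197 of the 200 high genes rose and 199 and 191 of the 200 low genes fell. Of 32 such tests 31 were called with the preset correlation.

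**Figure D3:**
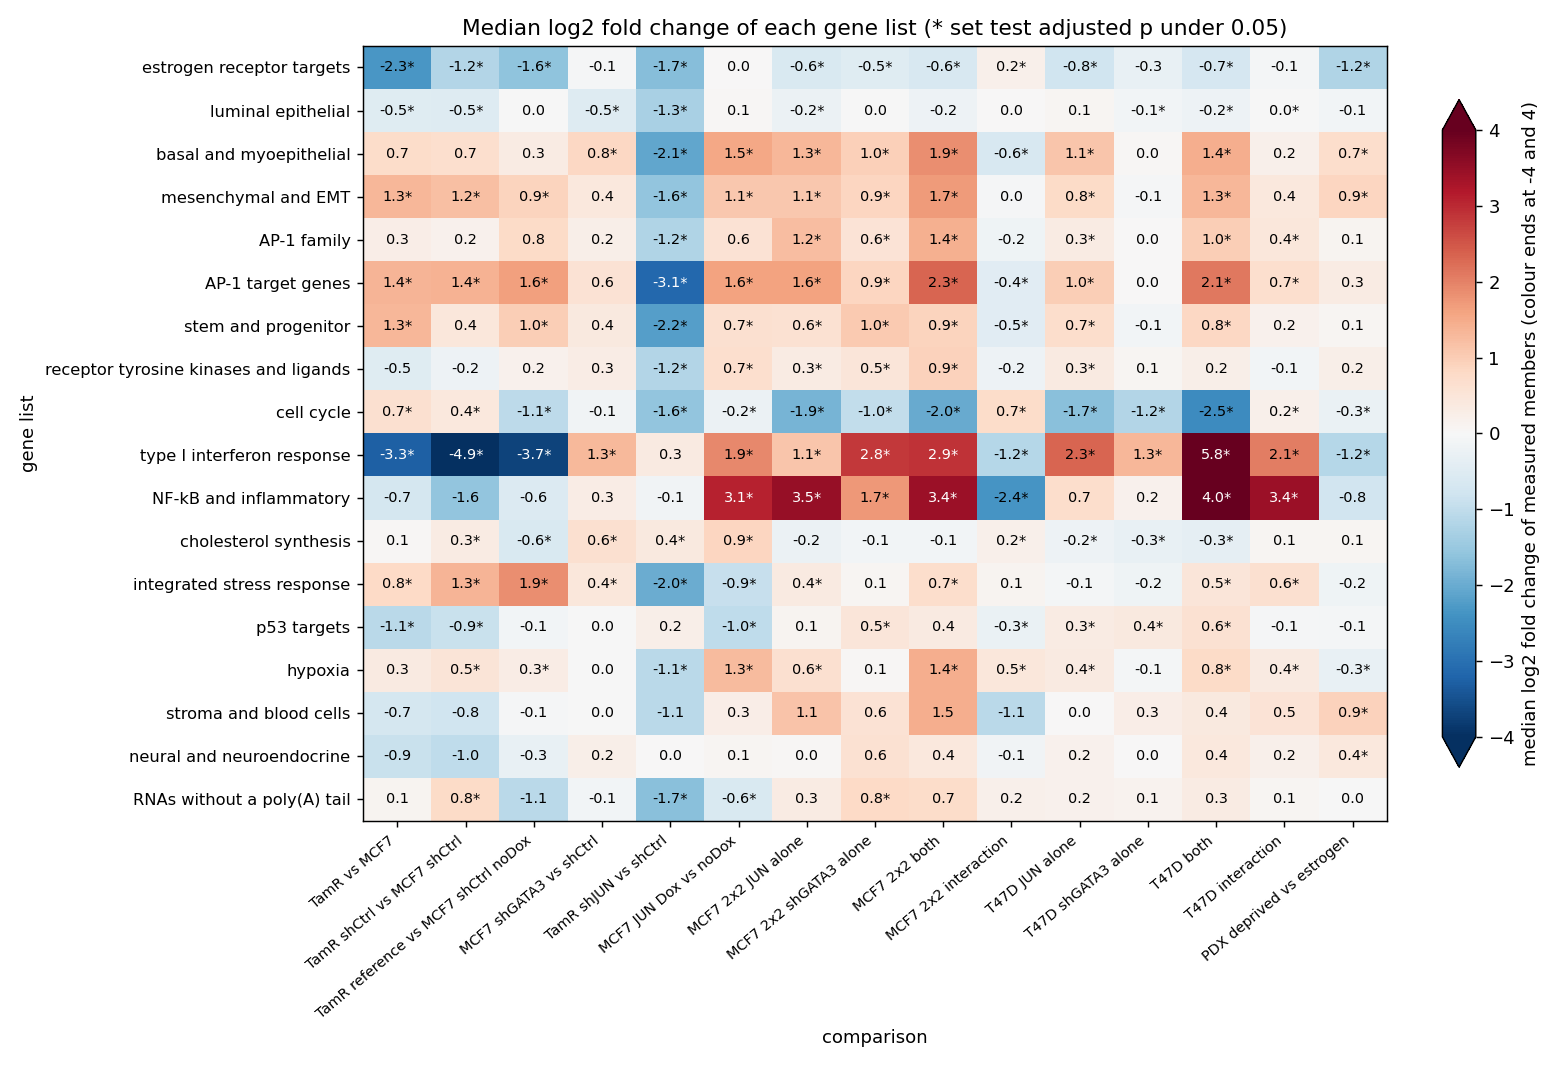
Median log2 fold change of the 18 gene lists (one line each) in the 15 comparisons (one column each). Colour runs from -4 to 4 and stars mark set tests with an adjusted p under 0.05, with GATA3 kept in the luminal list and JUN in the AP-1 family. The interferon list is lowest in TamR with the scrambled shRNA (-4.86) and highest in T47D with both changes (5.80).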

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

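The list tests of the difference between the lines, the test of the JUN interaction and the share of opposite members were chosen after the results were seen. The test of the combined change per gene was planned, and the floor and linear-scale tests were written before their values were known.

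The response to the combined GATA3 knockdown and JUN induction differed between T47D and MCF7 for 6842 of 13803 genes (4527 with DESeq2), 1244 of them by at least 2-fold and 20 in opposite directions at 2-fold in each line. By smallest adjusted p the first were interferon genes: the log2 change in T47D minus MCF7 was 3.72 ± 0.0475 (SE) for IFI6, 4.69 ± 0.0630 for IFIT1, 1.67 ± 0.0258 for STAT1, 2.97 ± 0.0473 for DDX58 and 4.07 ± 0.0652 for OAS2. Over the interferon list the median difference was 2.87 with both changes (adjusted p = 1.62e-17, 38 of 38 higher in T47D). In the interaction it was 3.20 (adjusted p = 1.28e-16, 38 of 38) and, for NF-kB genes, 4.73 (adjusted p = 3.39e-07, 22 of 23). Low counts were not checked for NF-kB genes. The response to JUN depended on GATA3 knockdown for 5616 genes in MCF7 and 5806 in T47D (3685 with DESeq2).

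The interferon interaction was negative in MCF7 and positive in T47D for 37 of 38 members. Low counts do not account for this, since 95.5% (21 of 22) of the members at 5 CPM or more in all 8 groups kept the opposite signs, and neither does the log scale, with 84.2% (32 of 38) opposite on linear CPM. JUN itself had a positive interaction in both lines (1.22 in MCF7, 0.99 in T47D), so a JUN excess in the combined arm of only one line is argued against. A hypothesis, not tested here, is that the lines differ in how GATA3 loss and JUN combine on interferon genes. GATA3 knockdown alone raised the list by 2.84 in MCF7 and 1.34 in T47D in the factorial experiments. In the stand-alone MCF7 experiment it raised the list by 1.31, so a contrast of that size also arose between 2 experiments in one line. Line and experiment cannot be separated with 1 factorial experiment per line, and the larger JUN induction in T47D, a response to lentivirus or doxycycline, and saturation in MCF7 stay open.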

How the results depend on the processing

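All alternatives here were planned, except leaving the manipulated gene out of lists, which was chosen after seeing the data. No count and no named gene reversed direction under any of them. DESeq2 kept 30 of 33 counts within 1.5 times. The other 3 were lower: 3685 genes against 5806 for the T47D interaction, 6104 against 9346 for the xenograft and 4527 against 6842 for the T47D minus MCF7 difference, and the cause was not tested. RLE size factors kept 34 of 34 counts within 1.5 times, no low-count filter 33 of 33, a fit of only the groups compared 34 of 34, leaving out each library 156 of 156, the 100-gene and 400-gene TamR lists both of theirs, and an estimated correlation 2 of 2. Of 154 list calls, RLE factors kept 153, only the groups compared 151 with 2 gained, and an estimated correlation 114. Beside the losses given in the report, a fit of the groups alone lost luminal genes in T47D with both changes (adjusted p = 0.115). Leaving the manipulated gene out of the lists that hold it (GATA3 or JUN) ended the call in 4 of 24 tests: beside the 2 given in the report, luminal genes in T47D with both changes (adjusted p = 0.119) and the AP-1 family in T47D with JUN (adjusted p = 0.385). Among values of named genes RLE factors left 391 of 391 on the same side of the threshold, DESeq2, no filter and only the groups compared 389 each, and leaving out libraries 1704 of 1712 (3 weaker, 5 stronger). JUN in TamR with the scrambled shRNA passed without the filter (0.13) and in the groups alone (0.13), and JUN in T47D with GATA3 knockdown passed without the filter (-0.47), in DESeq2 (-0.48) and in the groups alone (-0.49). The changes on leaving out a library concern the small interactions of GATA3 and ESR1. GATA3 in MCF7 ended its call in DESeq2 (-0.11) and without MCF7_shCtrl_Dox replicate 2 (-0.11), MCF7_shGATA3_Dox replicate 1 (-0.10) or MCF7_shGATA3_noDox replicate 2 (-0.10). ESR1 in MCF7 gained one without MCF7_shCtrl_noDox replicate 1 (-0.13), MCF7_shCtrl_Dox replicate 1 (-0.12), MCF7_shGATA3_Dox replicate 2 (-0.13) or MCF7_shGATA3_noDox replicate 2 (-0.12), and GATA3 in T47D without T47D_shGATA3 replicate 1 (0.20). Leaving out a library leaves 1 in its group, which is assumed to vary like the other groups.

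Replicate numbers did not pair the samples: the correlation of same-numbered deviations had a median of 0.00594 over 78 pairs of groups in MCF7 and TamR (-0.0690 to 0.151, 3 over 0.1), 0.00919 over 6 in T47D and -0.0383 in the xenograft. With the replicate number as a block 32 of 32 counts stayed within 1.5 times (TamR against MCF7 11820 against 11864), 378 of 379 named-gene values and 143 of 145 list calls stayed. The other 2 were basal genes in the xenograft (adjusted p = 0.0673) and luminal genes in the T47D interaction (adjusted p = 0.0629), and 2 list calls were gained. No paired analysis was possible for the reference TamR set because its groups share no replicate number. Depth limits low genes: 3 counts correspond to 0.0988 CPM in the deprived and 0.0940 in the estrogen xenograft group, and a gene without counts is not detectable below such a floor rather than absent.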

Other observations

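All differences between experiments below, and the kit and heterogeneity tests, were chosen after the results were seen, and the tests of scaling were written before theirs.

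Experiments of the same kind in MCF7 differed by gene group. GATA3 knockdown moved the p53 targets by a median of -0.024 and 0.48 (adjusted p = 1.37e-05) in the stand-alone and factorial experiments, NF-kB genes by 0.28 and 1.75 (adjusted p = 3.23e-05) and cholesterol synthesis genes by 0.64 and -0.12 (adjusted p = 6.11e-10). In TamR against MCF7 the cholesterol list stood at 0.060 and -0.62 (adjusted p = 2.29e-08) in the first and the reference set, and JUN induction raised interferon genes by 1.92 and 1.10 (adjusted p = 3.63e-09). RNAs without a poly(A) tail, which depend on the library kind, also differed, at -0.096 and 0.78 (adjusted p = 0.0237) in the GATA3 knockdowns and 0.12 and -1.08 (adjusted p = 0.00177) in TamR against MCF7. For the JUN inductions, at -0.62 and 0.34, the difference of this list did not pass (adjusted p = 0.0634). In each of these pairs the factorial or reference libraries hold little small RNA and the others much, so library kind and experiment are not separated.

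In the deprived xenograft, ALB, the main plasma protein made by liver, stood at 3627 ± 56.1 CPM of the total against 10.1 ± 0.333. The liver transcripts APOB and TTR had no counts in the 4 libraries and APOA1 none in the deprived group, below a floor of 0.0988 CPM, while SERPINA1, also on the estrogen receptor list, was at 207 ± 0.555 against 2196 ± 7.91. These 5 genes were chosen after ALB was seen.

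Cell cycle genes were higher in TamR in 2 sets (medians 0.65 and 0.43) and lower in the reference set (-1.05). Both groups of that set lack small RNA (0.415 and 0.937 CPM, 2.26-fold apart, against at least 2333 in the other kind of library). This argues against different kits for these 2 groups. The other 2 sets are of that other kind, so library kind is not separated from the change of sign between sets. With RLE factors the median was -1.06, so the choice of RLE or TMM factors does not account for the fall. A scaling error shared by both was not tested. RNAs without a poly(A) tail, of which most are histones, also differed between the sets (medians 0.12, 0.77 and -1.08, adjusted p = 0.00177 and 1.35e-04 against the reference set), so uneven poly(A) selection stays open. A candidate explanation is the growth state of the cultures when collected, such as confluence or time since passage, or the lentiviral and shRNA steps that the control in this set had and the reference TamR libraries lack. Growth state is not recorded, the shRNA labels differ exactly as the groups do, and neither was tested, so both stay open.

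Stroma and blood cell markers were higher in the deprived xenograft. With RLE factors 85% (17 of 20) were still higher, so the choice of RLE or TMM factors does not account for the rise. A scaling error shared by both was not tested. A larger share of non-tumour cells stays open. The log2 changes of the 20 members differed by more than their errors (chi-square per degree of freedom 31.0), but those errors come from 2 close libraries per group, and baseline expression in tumour cells would make the changes unequal too, so this does not exclude it. A change in one non-tumour cell type, mouse host reads counted as human, and expression of these genes by the tumour cells could each account for it and were not tested.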
